A study of Danio rerio with 19 samples.

How the data were processed

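The deposited series holds 19 zebrafish samples, 1 per group: 4 RNA libraries (sperm, egg, 1k-cell and germ ring), 4 hMeDIP samples (sperm, 2-cell, 16-cell and 1k-cell), 1 input sample from 16-cell embryos, 9 bisulfite samples and 1 TAB sample. The bisulfite, TAB and input data were not analysed here beyond the input's use in the authors' peak calls. Groups were taken from the sample titles.

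The RNA tables hold a normalized signal per gene, which the authors made, per the file headers, by scaling the read count of each gene with the TMM method; the labels name BWA 0.6.1-r104, edgeR and the Zv9 (danRer7) build. The counting tool, the annotation and the filters are not given in the sources used here. In each deposited table every value is a whole multiple of 1 step within 0.01 reads, for 100% of the values, so the authors' scaling used 1 factor per library and the read counts can be recovered. The step is 0.993 in sperm, 1.985 in egg, 0.951 at the 1k-cell stage and 1.507 at the germ ring stage, and 3 reads correspond to 2.98, 5.95, 2.85 and 4.52. The recovered totals are 21138688, 9241829, 24256918 and 14753999 reads.

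The hMeDIP lists were made by the authors with MACS 1.4.2, per the file headers, from tags aligned to Zv9, with a p cutoff of 1e-05, a band width of 200 bp, an effective genome size of 1400000000 bp and 1 tag kept per position, each against the 16-cell input. The tag counts per region are deposited as whole numbers made by the authors without normalization. The -10*log10(p) values are the authors' deposited -log10 p scores from MACS, multiplied by 10. The fold enrichment in the deposited lists is the authors' ratio of tags at the summit to the local expectation. The FDR in percent in the deposited lists was computed by the authors by swapping sample and control, and is 100% for all 165 regions. Kept tags numbered 9765379 for sperm, 8748086 for 2-cell, 10783174 for 16-cell and 10117040 for 1k-cell embryos, and 4230716 for the input. Folds were used only to order regions within a list, and scores were pooled over the lists for 1 stricter threshold.

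Each RNA table held 15328 entries for 14244 gene names; for the 718 names with several entries the entry with the highest total was used. A current symbol was found for 13618 names in the gene name table and not for 626. There are 464 names that share all 4 values with another name, and near-identical copies such as egg coat, globin and keratin genes may share reads. Genes at 0 in all 4 libraries numbered 547.

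Ratios are log2 of the normalized value plus 1 in one library over that in the other, for genes at 10 or more in either library, with a cutoff of 2-fold. The comparisons were egg against sperm, 1k-cell against egg, germ ring against 1k-cell and germ ring against egg. With 1 library per group no test was run and no p-value is given. Counting error is given as the exact (Clopper-Pearson) 95% interval of the ratio of recovered reads, and a fold against 0 reads is a bound at 3 reads. Such a bound, written as "at least", leaves out the counting error of the other library. The lower limit of the exact interval is smaller, as for tert at the 1k-cell stage against egg (44.4 against a bound of 54.9).

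Before the data were examined 22 gene lists were fixed: DNA methylation and demethylation, germ plasm, piRNA and meiosis, oocyte and egg, sperm flagellum and testis, first-wave zygotic, gastrula mesoderm, endoderm and organizer, maternal pluripotency-type transcription factors, replication, cell cycle, ribosomal protein, proteasome, oxidative phosphorylation, glycolysis, Hox cluster, Polycomb and Trithorax, linker and variant histones, stress and apoptosis, and markers of testis somatic cells, ovarian follicle cells, liver, red blood cells and skeletal muscle. An epidermis list and an exocrine pancreas list were added after the data were seen. A list's median is placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, for lists with at least 5 members above the floor. The naming rule, also fixed beforehand, took the 10 genes with the highest and the 10 with the lowest ratio, the 2 highest and 2 lowest of each list, and a fixed set around DNA methylation, germ cells and early regulators; clone-type names were left out of the extremes.

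Regions were shared when they overlapped by at least 1 bp (bedtools 2.31.1). Alternatives were other pseudocounts (0.1 and 5), floors (none and 50), a 4-fold cutoff, median-of-ratios, upper-quartile and equal-total scaling, other detection limits, a stricter region score, chromosomes 1 to 25 alone, and a reciprocal overlap of 50% or a distance of 1000 bp. The procedure was tested on simulated data in which 200 genes well above the floor were changed 4-fold, with counting noise alone and no shift in scaling. All 200 were recovered in each comparison, and 158 to 282 unchanged genes passed 2-fold, nearly all with a mean under 50. This checks the arithmetic only. It gives no error rate for single libraries, which can also differ by animal and by scaling. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Genes at the hMeDIP regions were not assigned, because no Zv9 annotation or genome sequence was used.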

Results

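The series holds 19 zebrafish samples, 1 per group, in which gametes and early embryos were profiled. RNA sequencing covered 4 of them: sperm, egg, embryos at the 1k-cell stage of the blastula, and embryos at the germ ring stage, when gastrulation begins. Pull-down of DNA carrying 5-hydroxymethylcytosine (hMeDIP), an oxidised form of methylated cytosine, covered sperm and embryos at the 2-cell, 16-cell and 1k-cell stages, and all 4 lists of enriched regions were called against 1 input sample from 16-cell embryos. The 9 bisulfite samples and the 1 TAB sample were not analysed here. No group has a replicate, so every difference below compares single libraries, without a test and without an estimate of the spread between animals. The intervals and floors given below cover counting error only.

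The RNA libraries held 21138688 recovered reads for sperm, 9241829 for egg, 24256918 for the 1k-cell stage and 14753999 for the germ ring stage. A single read was worth 0.993, 1.985, 0.951 and 1.507 normalized counts in these libraries, in the same order. At a normalized count of at least 10, the sperm library held 12319 of the 14244 gene names, the egg library 9640, the 1k-cell library 10123 and the germ ring library 10461. The median gene had a normalized count of 342 in sperm, 69.5 in egg, 214 at the 1k-cell stage and 172 at the germ ring stage. The 100 most abundant genes took 20.8% of the sperm total, 25.9% of the egg total, 14.3% of the 1k-cell total and 23.9% of the germ ring total. The highest normalized count belonged to actb2 in sperm (121297), cldnd in egg (285730), the gene listed as zgc:193933, now named nanog, at the 1k-cell stage (77955), and eef1a1l1 at the germ ring stage (267294).

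Across 12681 genes, which are not independent replicates, the 1k-cell and germ ring libraries had the highest Spearman correlation of the 6 pairs (0.871), followed by egg and 1k-cell (0.869) and egg and germ ring (0.796). The sperm library correlated at 0.762 with the 1k-cell library, 0.722 with egg and 0.718 with germ ring.

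The comparison of egg with sperm asks which transcripts each gamete library carries. The library labelled sperm also held marker transcripts of oocytes and other tissues, given below, so its values may not be those of sperm cells alone. Genes of the sperm tail and of late sperm development stood out in sperm: all 51 measured genes of the flagellum and testis list were at least 2-fold lower in egg, with a median log2 ratio of -9.34, or -8.62 with genes at 0 set to their bound; under median-of-ratios scaling 47 were at least 2-fold lower and none higher. The alpha tubulin tuba7l had a normalized count of 62611 in sperm and no read in egg, which makes it at least 10516-fold lower. The heat shock factor hsf5 was at least 2356-fold lower and the axonemal dynein dnah9 at least 1195-fold lower. The meiotic chromosome axis gene hormad1 had 5239 in sperm and 11.9 in egg, the recombinase dmc1 was at least 153-fold lower in egg, and the piRNA pathway gene piwil1 was 53.5-fold lower (11148 against 208).

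In the list of germ plasm, piRNA and meiosis genes, 16 of 25 measured members were at least 2-fold lower in egg and 1 was higher, with a median log2 ratio of -2.53 (14 lower and 5 higher under median-of-ratios scaling). The 1 as deposited was dazl, a germ cell RNA-binding protein gene, 5.56-fold higher in egg (21621 against 3889). The germ cell helicase gene vasa had 3701 in egg and 6751 in sperm, but a log2 ratio of 0.40 under median-of-ratios scaling. Among regulators and maternal products, cth1 was 5.40-fold higher in egg (160517), the deadenylation factor gene btg4 4.64-fold, eomesa 14.6-fold, the cyclin gene ccne1 22.0-fold, pou5f1 (now pou5f3) 11.9-fold and nanog 3.30-fold (73460 against 22230). The list of maternal pluripotency-type transcription factors had 4 of 13 members higher and 4 lower, with a median log2 ratio of -0.15 that turned to 1.11 under median-of-ratios and 0.91 under upper-quartile scaling. Its lower members included tcf7l1b (18.5-fold) and ctcf (7.24-fold), which stayed lower under median-of-ratios scaling (log2 ratios -2.94 and -1.59).

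The library labelled sperm also held high levels of transcripts known from oocytes. Of 31 measured oocyte and egg genes, 18 were at least 2-fold lower in egg than in sperm and 8 were higher, with a median log2 ratio of -2.20; under median-of-ratios scaling 14 were lower and 12 higher. All 10 egg coat (zona pellucida) genes in this list were lower in egg, among them zp2.2 (20360 in sperm and 61.5 in egg) and zp2.5 (19976 and 173). Outside the naming rule and chosen after their values were seen, zp3b had 58594 in sperm and 1137 in egg, and zar1, an oocyte gene, had 36298 and 322. Some copies of these egg coat genes are near identical, so reads may be shared among them.

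Marker lists of other cells were lower in egg than in sperm. Their median normalized counts in sperm were 1304 for exocrine pancreas and 672 for red blood cells, above the library's median gene, and 267 for liver, 129 for testis somatic cells, 81.5 for follicle cells and 77.5 for muscle, below it. Of 13 measured red blood cell genes all were at least 2-fold lower in egg (median log2 ratio -10.17, or -7.59 at the bound). The globin hbaa1 had 34337 in sperm and 1 read in egg, a ratio of egg to sperm of 5.78e-05 with a 95% counting interval of 1.46e-06 to 0.000322. The globin names ba1 and ba2 share the same values, and reads of globin copies may be shared. Of 20 testis somatic cell genes 17 were lower in egg, among them insl3, a hormone gene of Leydig cells, at least 1627-fold, and star, of steroid hormone synthesis, at least 165-fold. The liver list had 20 of 21 members lower, the skeletal muscle list 17 of 17, and the ovarian follicle list 11 of 13. An exocrine pancreas list, added after the data were seen, had all 13 members lower (median log2 ratio -10.29), and the protease gene try, named by the rule, was at least 1865-fold lower. The macrophage and neutrophil lysozyme gene lyz was at least 1165-fold lower.

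Among the genes with high ratios in egg, the keratin gene krt5 was 17.6-fold higher (109093 against 6201), cyp7a1a, a cytochrome P450 gene of bile acid synthesis, 48.6-fold, the integrin genes itga6b 46.2-fold and itgb4 34.2-fold, il13ra2 56.5-fold, and scpp7 at least 37.3-fold. In an epidermis list added after the data were seen, 19 of 37 members were at least 2-fold higher in egg and 10 lower (median log2 ratio 1.05).

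For genes of energy metabolism and protein turnover the median log2 ratio was -3.31 for glycolysis (25 of 29 members lower), -3.03 for oxidative phosphorylation (74 of 93), -2.86 for the proteasome (40 of 45) and -2.09 for ribosomal proteins (75 of 80). Under median-of-ratios scaling 20, 65, 30 and 32 members of these lists were lower. The DNA methylation and demethylation list had 13 of 21 members lower and 3 higher, and 7 lower and 5 higher of 20 under median-of-ratios scaling. Within it, dnmt1, the maintenance DNA methyltransferase gene, was 4.83-fold higher in egg (58757 against 12178), with a 95% counting interval of 4.72 to 4.93, and dnmt7 (now dnmt3ba) was 5.16-fold higher. The dnmt4 gene (now dnmt3bb.1) had 512 in egg and 523 in sperm, a log2 ratio of -0.03 that was 1.23 under median-of-ratios scaling, and dnmt3 (now dnmt3bb.2) was 2.31-fold lower in egg, but had a log2 ratio of 0.06 under median-of-ratios scaling. The replication gene mcm6 had 2 reads in egg and 3029 normalized counts in sperm, and the replication list turned from a median log2 ratio of -0.95 to 0.32 and 0.12 under median-of-ratios and upper-quartile scaling. The median log2 ratios of the remaining lists were 0.28 for cell cycle, -1.43 for Polycomb and Trithorax, -1.52 for stress and apoptosis, -1.82 for linker and variant histones, -1.90 for first-wave zygotic genes, -2.29 for Hox genes and -2.54 for gastrula genes.

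Over all 12443 genes compared, 1777 were at least 2-fold higher and 7625 at least 2-fold lower in egg, with a median log2 ratio of -1.80. The ratio also depends on expression level: random lists matched on expression had medians from 0.72 for the ribosomal protein list, which lay at percentile 0 of them, to -4.01 for the Hox list, which lay at percentile 99.99. Under median-of-ratios scaling the split was 3668 higher and 5318 lower, with a median log2 ratio of -0.49, and under upper-quartile scaling 3325 and 5707.

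**Figure D1:**
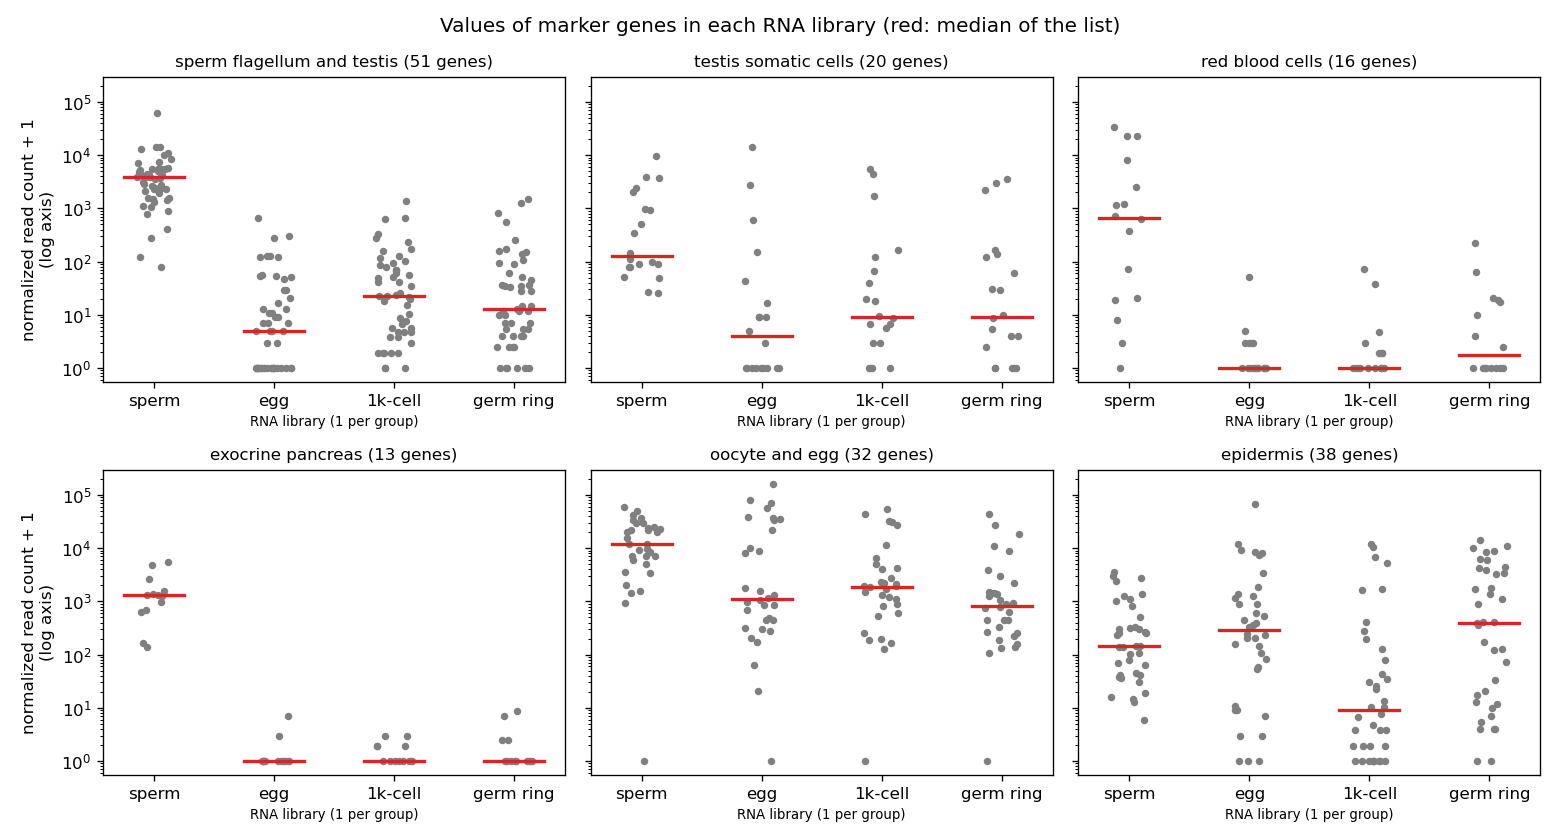
Each panel plots the normalized read count plus 1 (log axis) of the genes of 1 marker list in the 4 RNA libraries, with a point per gene and a red line at the median of the list. Median normalized counts in the sperm library were 3863 for flagellum and testis genes, 672 for red blood cell genes, 1304 for exocrine pancreas genes and 12123 for oocyte and egg genes, and the median epidermis gene had 287 in egg and 8.08 at the 1k-cell stage.

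The comparison of the 1k-cell stage with egg covers cleavage, when embryos rely on RNA from the egg and transcription of their own genome is starting. Several regulators of the blastula were higher at the 1k-cell stage: ctcf, of chromatin insulation, was 46.7-fold higher (38641 against 828), sox19b 13.2-fold (48352 against 3674), the de novo DNA methyltransferase genes dnmt3 10.4-fold and dnmt4 7.79-fold, and the Polycomb gene phc2a 17.2-fold. The telomerase gene tert had 327 and no read in egg, at least 54.9-fold higher, pih1d1 was at least 37.5-fold higher, and taf1a was 151-fold higher over 4 reads in egg. With 1 read in egg, heatr1 was 275-fold higher (95% counting interval 49.2 to 10898). Median-of-ratios scaling moves the log2 ratios of this comparison by about -1.28, and upper-quartile scaling by -1.34.

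Among the genes with the lowest ratios at the 1k-cell stage, the keratin gene krt5 was 1319-fold lower (82.7 against 109093) and krt15 at least 669-fold, the claudin genes cldni at least 843-fold and cldna at least 228-fold, the collagen genes col1a2 at least 630-fold and col1a1b 395-fold, and cyp7a1a 437-fold. The sparc gene had 1 read at the 1k-cell stage and was 687-fold lower, with a counting interval of the 1k-cell to egg ratio from 3.68e-05 to 0.008. Of the 30 measured members of the added epidermis list, 21 were at least 2-fold lower and 1 was higher, with a median log2 ratio of -4.85, or -6.10 relative to all genes.

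In the oocyte and egg list 8 of 31 members were lower and 9 higher as deposited, and 19 lower and 3 higher under median-of-ratios scaling, with a median log2 ratio of -0.11 as deposited, -1.39 under median-of-ratios and -1.45 under upper-quartile scaling, or -1.35 relative to all genes (percentile 0.47 among random lists of matched expression). The gene now named zar1l, listed under a clone name, was 30.1-fold lower (1923 against 57959) and org 9.38-fold lower, while npm2a, of sperm chromatin remodelling, was 26.6-fold higher. The germ plasm list had 10 of 23 members higher and 6 lower, and 6 higher and 9 lower under median-of-ratios scaling. In it dazl was 16.4-fold lower (1321 against 21621), and asz1 was 19.9-fold, tdrd5 19.1-fold and piwil1 6.20-fold higher. The cell cycle and replication lists had medians of 0.09 and 1.21, which were -1.19 and -0.38 under median-of-ratios scaling. The checkpoint gene bub3 was 163-fold lower (136 against 22159), aurkb 16.5-fold, top2a 26.2-fold and cdc45 17.1-fold, whereas mcm5 was 22.1-fold higher.

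Of 28 Polycomb and Trithorax genes 18 were higher and 3 lower, with a median log2 ratio of 2.13 (percentile 99.90), and 13 of 27 were higher and 8 lower under median-of-ratios scaling; cbx8b was 19.2-fold higher. Ribosomal protein genes were low against all genes, with 23 of 80 at least 2-fold lower (78 under median-of-ratios scaling), 1 higher and a median log2 ratio of -0.77, or -2.01 relative to all genes; rplp0 was 2.90-fold lower. For the DNA methylation list the median log2 ratio was 1.42 as deposited, -0.15 under median-of-ratios and -0.21 under upper-quartile scaling. Of its members dnmt1 was 2.12-fold lower (27780 against 58757), dnmt8 (now dnmt3aa) 4.66-fold higher, and dnmt7 and dnmt5 (now dnmt3bb.3) were within 2-fold at 4629 against 3638 and 2163 against 1508; under median-of-ratios scaling dnmt8 was within 2-fold (log2 ratio 0.93) and dnmt7 (-0.94) and dnmt5 (-0.76) turned. The pluripotency-type factors had a median log2 ratio of 1.05, which was -0.23 and -0.29 under median-of-ratios and upper-quartile scaling. The nanog gene was at 77955 against 73460 and pou5f1 at 41838 against 22524, and both turned under median-of-ratios scaling (log2 ratios -1.20 and -0.39). The chaperone gene hspa5 was 13.7-fold higher and fos 37.2-fold lower.

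The first-wave zygotic list had 16 of 33 members higher and 10 lower at this stage (10 of 34 higher and 19 lower under median-of-ratios scaling), with a median log2 ratio of 0.17 that was -1.25 under upper-quartile scaling and likewise negative under median-of-ratios scaling. Its lower members included krt5 (82.7 against 109093), krt4 (19.0 against 5146) and apoeb (53.2 against 7411), which belong to the pattern in the egg library weighed under other observations. Within the early zygotic set vox had 71.3 at the 1k-cell stage and no read in egg, and aplnrb was at least 9.90-fold higher. Of the gastrula genes msgn1 was at least 14.8-fold and pcdh8 at least 13.1-fold higher. Median log2 ratios were 1.47 for the proteasome, 1.03 for glycolysis, 0.61 for oxidative phosphorylation, 0.29 for Hox genes, 0.04 for histones, 0.02 for stress and apoptosis and 2.38 for flagellum and testis genes, and 24 of 43 gastrula genes were higher and 8 lower (14 and 17 of 46 under median-of-ratios scaling). Of these, median-of-ratios and upper-quartile scaling turned the direction for glycolysis, oxidative phosphorylation, Hox, histone, stress and gastrula genes, as they did for the germ plasm, cell cycle, replication and testis somatic lists. The flagellum median rests on low counts: 18 members reached 10 in egg and 31 at the 1k-cell stage, where the list medians were 3.97 and 21.9. It was 1.91 at the bound, and matched random lists had a median of 1.64 (percentile 92.5). Of the other-tissue lists, testis somatic cells had 9 measured members (5 higher, 2 lower), muscle 7 (6 and 1) and follicle cells 5 (1 and 4).

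Over all 10685 genes compared, 5840 were at least 2-fold higher and 1338 at least 2-fold lower at the 1k-cell stage, with a median log2 ratio of 1.24. Under median-of-ratios scaling the split was 3246 higher and 3683 lower, with a median log2 ratio of -0.14, and under upper-quartile scaling 3122 and 3814.

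The comparison of the germ ring stage with the 1k-cell stage covers activation of the embryo's genome and the onset of gastrulation. Most zygotic genes were higher: 40 of 42 first-wave genes were at least 2-fold higher and none lower, with a median log2 ratio of 7.14 (percentile 100). Of 64 gastrula mesoderm, endoderm and organizer genes 57 were higher, with a median of 5.73, and 3 were lower, among them otx1b (9.8-fold) and evx1 (5.2-fold). The T-box gene tbx16 had 20401 and no read at the 1k-cell stage, at least 7153-fold higher, and ntla (now tbxta), of the notochord and tail, had 11258 against 1 read, a ratio of 11841 with a counting interval of 2125 to 467748. The ventral homeobox gene vox was 128-fold higher, the organizer gene gsc 72.0-fold and the endoderm factor foxa3 at least 2467-fold. The highest ratios of the first-wave list included the keratin gene krt18 at 54807 against 4 reads (14412-fold) and the claudin gene cldne at 25974 against 2 reads (13660-fold, counting interval 3781 to 112804). Outside the lists, asb11 was at least 5734-fold, alcamb at least 3180-fold and sult6b1 at least 2776-fold higher.

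The ribosomal protein list was shifted upward at the germ ring stage, with a median log2 ratio of 0.92 (percentile 100). Of 81 members 38 were at least 2-fold higher, 42 lay between and 1 was lower (63 higher and none lower under median-of-ratios scaling). The genes rpl4 and rplp0 were each 4.20-fold higher. The proteasome had a median log2 ratio of 0.51 and linker and variant histones 1.25, with h2afx 10.9-fold higher. Of 21 stress and apoptosis genes 11 were higher and 4 lower, among them jun 92.7-fold. The cyclin genes ccnd1 (238-fold) and ccne2 (117-fold) and the replication genes mcm6 (475-fold) and mcm3 (83.8-fold) were higher, although the cell cycle and replication lists had median log2 ratios of -0.22 and -0.41, which were 0.30 and 0.11 under both median-of-ratios and upper-quartile scaling. Direction also turned for oxidative phosphorylation (-0.05 as deposited, 0.47 rescaled) and glycolysis (-0.33 and 0.18).

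In the oocyte list none of 31 members was at least 2-fold higher, 19 lay between and 12 were lower, among them mos (7.43-fold) and the gene listed as zgc:158856, now slbp2 (9.48-fold). The list's median log2 ratio was -0.59 (percentile 25.7), against -0.43 for all genes. None of the 22 germ plasm genes was higher, 11 lay between (median log2 ratio -0.97, percentile 7.51) and 11 were lower, among them tdrd1 (4.36-fold) and dazl (3.46-fold), while vasa was at 6783 against 5450. Of 28 Polycomb and Trithorax genes 14 were lower and none higher (median log2 ratio -1.01), while under median-of-ratios scaling 10 of 27 were lower and 4 higher (-0.54). The genes cbx8b (13.1-fold) and phc2b (6.02-fold) were lower. Of 13 Hox genes above the floor 8 were lower, but all 13 passed the floor in the 1k-cell library and only 8 in the germ ring library. Passing through the 1k-cell library favours lower ratios, so no fall of Hox genes is read from this. The median over all 48 Hox genes was 3.33 at the 1k-cell stage and 1.51 at the germ ring stage. The pluripotency-type list had 2 of 13 members higher and 6 lower, and 4 higher and 3 lower under median-of-ratios scaling. Of its members smad2 (8.75-fold), sox19b (7.17-fold) and nanog (2.21-fold) were lower, whereas ctcf (2.18-fold) and foxh1 (2.11-fold) were higher and pou5f1 stood at 80736 against 41838. Under median-of-ratios scaling nanog was within 2-fold (log2 ratio -0.63) and pou5f1 past it (1.47).

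The DNA methyltransferase genes went both ways: dnmt1 was 5.73-fold lower (4851 against 27780), while dnmt3 was 2.07-fold higher (8534 against 4126) and dnmt7 2.37-fold (10988 against 4629). Of the other de novo genes dnmt6 (now dnmt3ab) was 4.10-fold lower on 8 reads, and dnmt4 (2430 against 3986), dnmt5 (1216 against 2163) and dnmt8 (139 against 166, but a log2 ratio of 0.26 under median-of-ratios scaling) stood lower within 2-fold. The demethylation-linked gene gadd45ba was 96.1-fold higher. The maintenance factor gene uhrf1 is listed at 0 in all 4 libraries, as is the oocyte gene figla, and since the annotation behind the counts is not given, this 0 is no evidence that uhrf1 was not expressed. The genes tet1, tet2 and tet3 have no value in the files. The genes with the lowest ratios stood at low levels: fam46bb was at least 12.2-fold, nr1h4 at least 9.68-fold and tlx1 at least 7.36-fold lower. In the germ ring library 5 red blood cell, 6 liver and 6 muscle genes reached 10, the highest being cahz at 221, while of the testis somatic and follicle lists cyp11a1 stood at 3541, hsd3b1 at 3036, cyp17a1 at 2233 and notch3 at 1644. The flagellum list had 15 of 33 members lower (8 under median-of-ratios scaling), and the epidermis list 21 of 32 higher.

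Over all 10917 genes compared, 1742 were at least 2-fold higher and 3732 lower at the germ ring stage, with a median log2 ratio of -0.43. Under median-of-ratios scaling the split was 2562 higher and 2408 lower, with a median log2 ratio of 0.10, and under upper-quartile scaling 2563 and 2394.

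**Figure D2:**
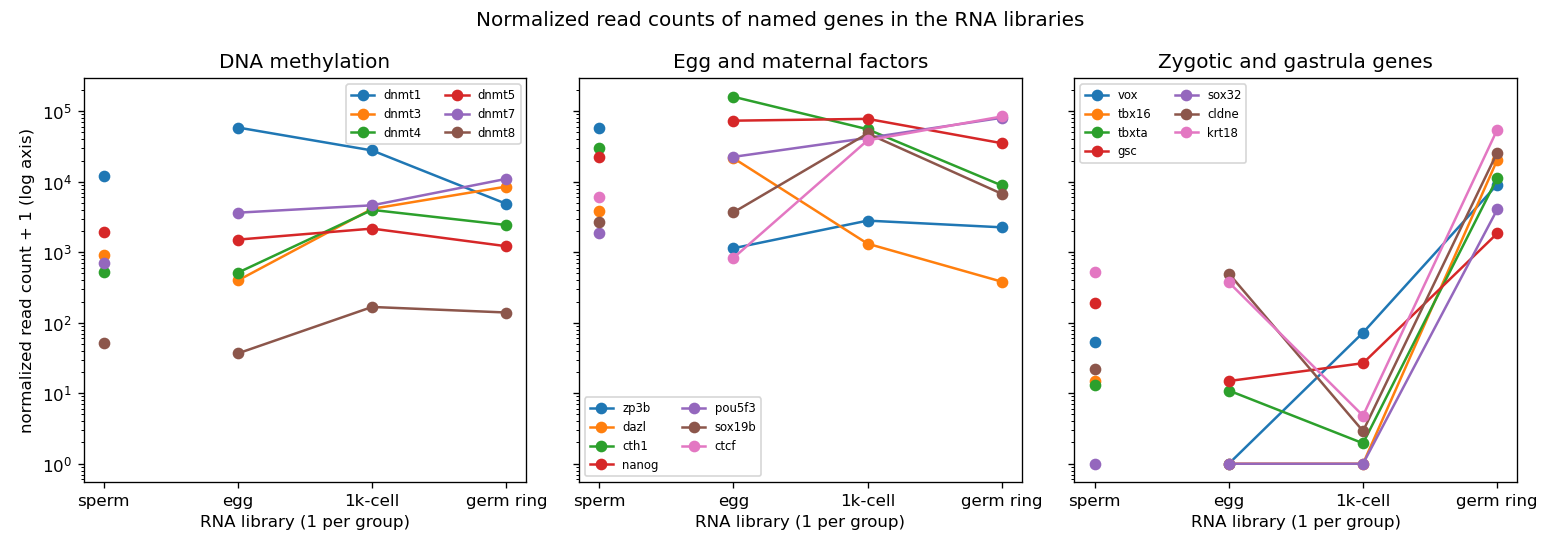
The 3 panels plot the normalized read count plus 1 (log axis) of named genes in the sperm, egg, 1k-cell and germ ring libraries, with 1 library per point and lines joining egg to the embryo stages. The dnmt1 gene stood at 58757 in egg and 4851 at the germ ring stage, dnmt3 at 397 and 8534, and tbx16 had no read in egg or at the 1k-cell stage and 20401 at the germ ring stage.

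The comparison of the germ ring stage with egg spans the whole interval from gamete to gastrula. The first-wave list had 40 of 42 members higher (median log2 ratio 7.28) and the gastrula list 57 of 66 (6.36). Against no read in egg, the otolith matrix gene stm was at least 3477-fold, tbx16 at least 3426-fold, nnr at least 1846-fold, vox at least 1533-fold, ved at least 1381-fold and the endoderm gene sox32 at least 679-fold higher. Of 20 DNA methylation and demethylation genes 13 were higher and 3 lower (median log2 ratio 2.09, percentile 98.5): dnmt3 was 21.5-fold and gadd45bb 333-fold higher, and dnmt1 was 12.1-fold lower. Of the other methyltransferase genes dnmt4 was 4.75-fold, dnmt8 3.88-fold and dnmt7 3.02-fold higher, while dnmt5 (1216 against 1508) and dnmt6 (12.1 against 17.9) stood lower within 2-fold. Under median-of-ratios scaling dnmt7 was within 2-fold (log2 ratio 0.83) and dnmt5 (-1.07) and dnmt6 (-1.26) were past it. The insulator gene ctcf was 102-fold higher and the Polycomb methyltransferase gene ezh2 11.8-fold.

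Egg transcripts that were lower at the germ ring stage included dazl (56.7-fold), sybu, a maternal axis gene (66.1-fold), zar1l (40.1-fold), bub3 (24.6-fold), aurkb (16.1-fold) and eomesa (9.82-fold). In the oocyte and egg list 11 of 31 members were lower, 5 higher and 15 between, with a median log2 ratio of -0.59 (percentile 0.26). Under median-of-ratios scaling 20 were lower and 3 higher. The cell cycle list was low against all genes, with 15 of 33 members lower and 11 higher and a median log2 ratio of -0.47, or -1.35 relative to all genes (percentile 0.68). Genes at no read in the germ ring library were cyp7a1a (at least 459-fold lower), krt15 (at least 422-fold), the antigen presentation gene cd74a (at least 274-fold), rbp4 (at least 237-fold), upk1a (at least 161-fold) and icn2 (at least 159-fold). In the epidermis list 12 of 35 members were higher and 12 lower. The keratin gene krt5, of the first-wave list, was 4.20-fold lower. Lists with medians between -1 and 1 whose direction turned under both rescalings were germ plasm (0.14 as deposited, -0.62 under median-of-ratios), pluripotency-type factors (0.14, -0.62), replication (0.24, -0.52), ribosomal proteins (0.21, -0.55), oxidative phosphorylation (0.83, -0.09), glycolysis (0.51, -0.25), Polycomb and Trithorax (0.55, -0.20) and epidermis (0.10, -0.68). The proteasome had a median log2 ratio of 2.02, linker and variant histones 1.16, stress genes 1.16 and Hox genes -1.64. The Hox value covers 16 of 48 genes, of which 13 reached 10 in egg and 8 at the germ ring stage.

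Over all 10971 genes compared, 5272 were at least 2-fold higher and 2167 lower at the germ ring stage, with a median log2 ratio of 0.88. Under median-of-ratios scaling the split was 3916 higher and 3615 lower, with a median log2 ratio of 0.04, and under upper-quartile scaling 3826 and 3719.

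**Figure D3:**
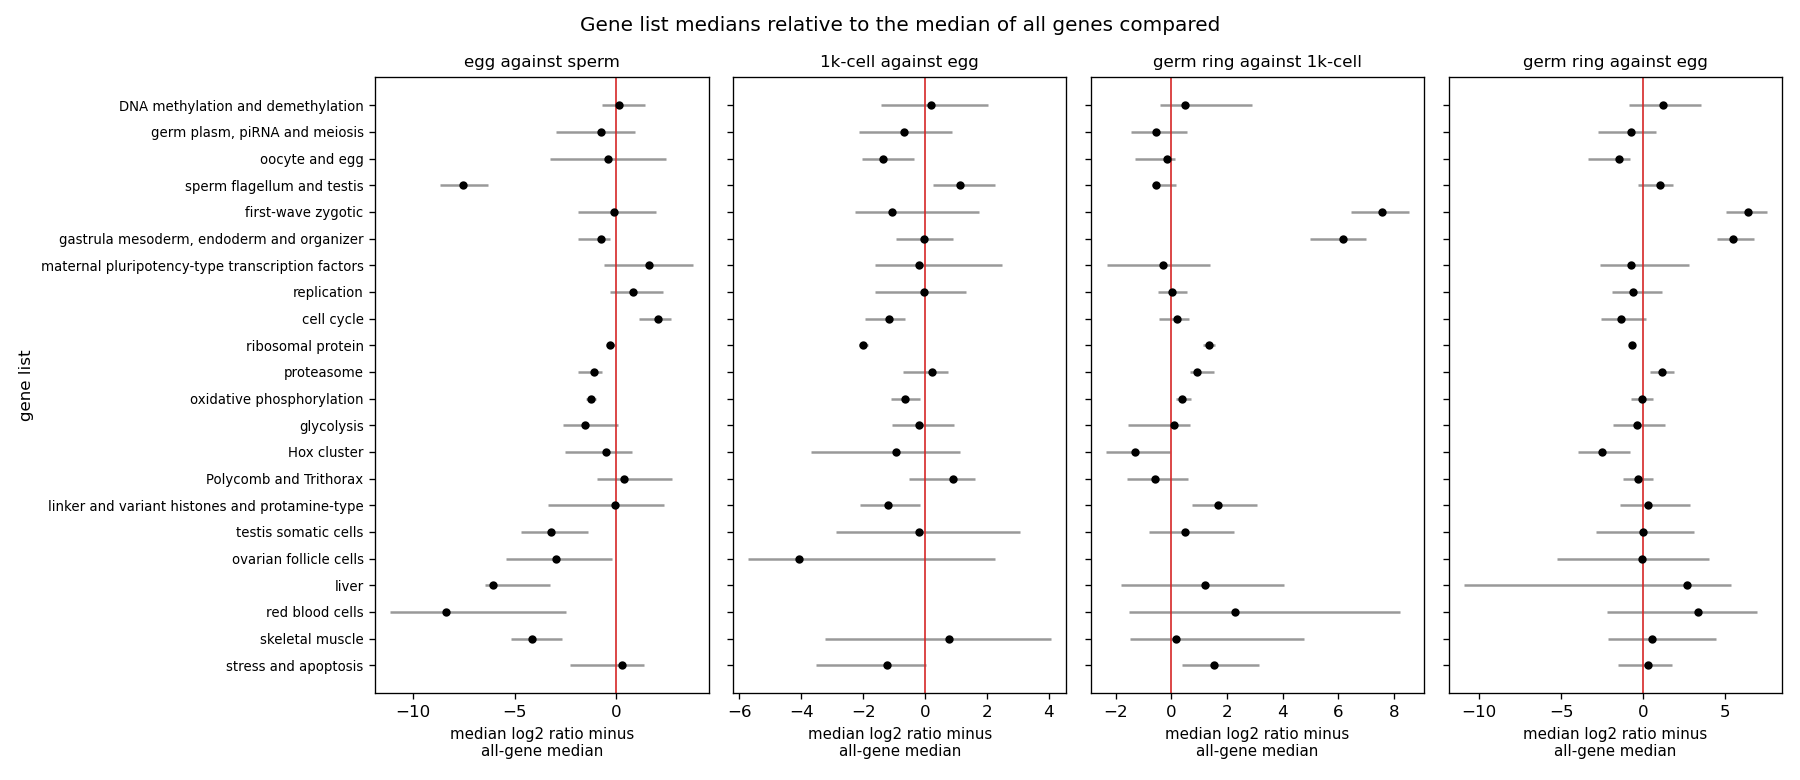
Points are the median log2 ratio of each fixed gene list with at least 5 members above the floor, minus the median of all genes, in the 4 RNA comparisons, and bars are 95% binomial intervals of the median over genes. A rescaling of a library moves most lists and the median of all genes together, so their distances from the red line at 0 change little. Lists with many members near 0 move less than all genes do. For egg against sperm the liver median was -7.88 as deposited and -7.54 under median-of-ratios scaling, while all genes went from -1.80 to -0.49. The first-wave list stands 7.57 above the line for germ ring against 1k-cell and the flagellum and testis list -7.53 from it for egg against sperm.

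The hMeDIP lists ask where 5-hydroxymethylcytosine was enriched in sperm and early embryos. The deposited lists held 60 regions for sperm, 67 for 2-cell embryos, 21 for 16-cell embryos and 17 for 1k-cell embryos, covering 49.5, 50.6, 18.7 and 13.9 kb of the Zv9 genome. These regions took 0.021%, 0.025%, 0.007% and 0.006% of the kept tags, which numbered 9765379, 8748086, 10783174 and 10117040, against 4230716 for the input. The median region held 32, 28, 32 and 34 tags and was 805, 744, 858 and 762 bp long. The authors' empirical false discovery rate was 100% for all 165 regions, so no region can be set apart from background by that measure.

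Merged across stages the lists gave 142 regions, of which 125 were in 1 list, 13 in 2, 2 in 3 and 2 in all 4. The regions found in all 4 lists were on chromosome 1 from 4792687 to 4793866 and on the unplaced sequence U from 24977995 to 24978421 (Zv9, 1-based). Those in 3 lists were on chromosome 3 from 10945405 to 10946423 and chromosome 6 from 24365525 to 24366760. The 2-cell list shared 6 regions with sperm, 7 with the 16-cell list and 7 with the 1k-cell list; sperm shared 3 with the 16-cell and 4 with the 1k-cell list, and the 16-cell and 1k-cell lists shared 4. Placing regions at random would give 0.0045 shared regions or fewer for each pair. That figure takes every position as equally likely, so it cannot tell shared enrichment from positions that gather tags in any sample. All lists used the same input, so part of the overlap may come from the shared control.

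By the authors' fold enrichment, the highest region in sperm lay on chromosome 20 from 50953968 to 50954667 (61.9-fold), and a region at nearly the same place was highest in the 2-cell list (50954015 to 50954645, 59.3-fold). In the 16-cell list the highest was on chromosome 2 from 4191463 to 4192231 (37.5-fold). In the 1k-cell list a region on chromosome 2 from 59346800 to 59347580 tied at 27.0-fold with the region on U from 24978000 to 24978403, which was found in all 4 lists. For 106 of the 165 regions (64.2%) the fold times the genome-mean background is a whole number within 0.02, as it would be for summit tags divided by that background and not by a local control. Genes at these positions are not given, since no annotation of this build was used.

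**Figure D4:**
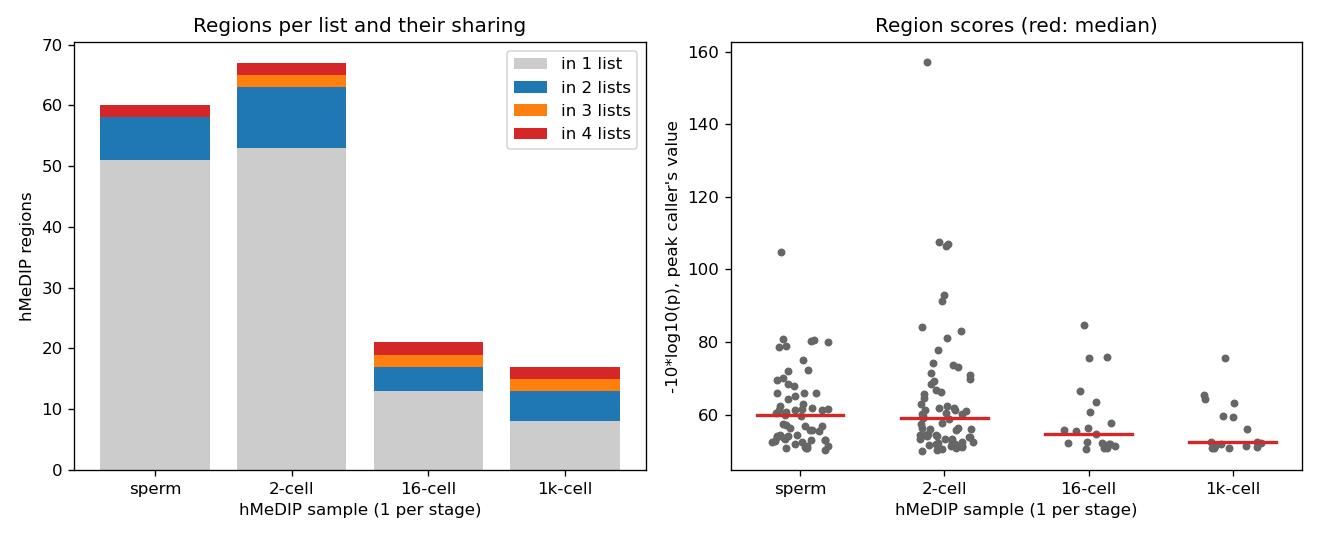
The left panel plots the number of hMeDIP regions per stage, coloured by the number of lists that hold them, and the right panel plots the peak caller's -10*log10(p) of each region, with a red line at the median. The 4 lists held 60, 67, 21 and 17 regions, and scores are shown for use within a list, since they depend on each list's depth and background.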

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

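The alternatives that use the counting interval, summed entries of a gene name, median-of-ratios without the sperm library, lists without other-tissue genes, thinned libraries and randomly placed regions were chosen after the data were seen. No paired analysis was possible because every group has 1 library. The counts of genes, and list medians near 0, depend on how the libraries are scaled: egg values stand low and 1k-cell values high against the median-of-ratios factors of 0.563 and 1.37. Median-of-ratios scaling gave 3668 genes higher in egg than in sperm, 3246 higher and 3683 lower at the 1k-cell stage than in egg, 2408 lower at the germ ring than at the 1k-cell stage, and 3615 lower at the germ ring stage than in egg. Upper-quartile scaling gave 3325, 3122 and 3814, 2394 and 3719 in the same places. Median-of-ratios without the sperm library gave 3337 and 3459 for 1k-cell against egg, 2474 lower for germ ring against 1k-cell and 3483 lower for germ ring against egg. For the egg to 1k-cell shift, equal totals alone left a median of 0.89, and removing abundant genes and thinning for depth left 0.71 and 0.82. For the other comparisons the cause was not tested.

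At a 4-fold cutoff 668 genes were higher in egg than in sperm, 3825 higher and 718 lower for 1k-cell against egg, 1117 and 1457 for germ ring against 1k-cell, and 3469 and 1149 for germ ring against egg, since fewer genes pass a larger fold. The other settings (pseudocounts, floors, equal totals, the counting interval past 2-fold, summed entries, and leaving out other-tissue genes) kept all 8 counts within 1.5 times. Leaving out other-tissue genes dropped few genes without rescaling, with 12275 of 12443 left for egg against sperm, so it could hardly move these counts. It does not test how other tissue in the material affects them.

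Between 1k-cell and egg, 7 list medians of at least 1 in size changed sign under median-of-ratios and upper-quartile scaling: DNA methylation (-0.15 and -0.21), gastrula (-0.27 and -0.33), pluripotency-type factors (-0.23 and -0.29), replication (-0.38 and -0.44), glycolysis (-0.25 and -0.31), testis somatic cells (-0.66 and -0.71) and liver with 4 measured members (2.52 as deposited, -0.02 and -0.08). Smaller medians also changed sign there for the oxidative phosphorylation, Hox, histone, stress, germ plasm, cell cycle and first-wave lists. Of 90 list medians, 59 stayed within their interval under median-of-ratios and 61 under upper-quartile scaling. The log2 ratio of dnmt3 for egg against sperm became 0.06 under median-of-ratios scaling; the other ratios past 2-fold of genes the report names kept their sign under both rescalings and a pseudocount of 5. Of the remaining genes past 2-fold that the naming rule took, tuba8l2 (0.17) and spag1 (0.02) for egg against sperm and h2afy (-0.17) and fga (-0.02) for 1k-cell against egg changed sign under median-of-ratios scaling.

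Over all features the Spearman correlations were 0.784 for sperm and egg, 0.816 for sperm and 1k-cell, 0.785 for sperm and germ ring, 0.892 for egg and 1k-cell, 0.838 for egg and germ ring and 0.896 for 1k-cell and germ ring. With a pseudocount of 5 Pearson's r was 0.752 for sperm and 1k-cell, 0.706 for sperm and germ ring and 0.87 for 1k-cell and germ ring. Above the median of the pooled region scores were 33 of 60 sperm, 37 of 67 2-cell, 7 of 21 16-cell and 6 of 17 1k-cell regions. The pooled median fixes how many pass in all, not the split over lists, and scores depend on each list's depth and background. Shared regions kept within 1.5 times under a 50% reciprocal overlap or 1000 bp. The egg library has the fewest reads, 9241829, so a count of 0 there allows up to 5.95 normalized counts.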

Other observations

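All tests below were chosen after the result they address was seen, except the epidermis test, whose list had not been looked at when it was written; that list itself was added after the data were seen. The weighing covers 3 patterns, and the design gives no biological test of any of them.

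The library labelled sperm holds oocyte transcripts at high levels, for example zp3b at 58594 and zar1 at 36298. Reads leaked from the egg library are argued against by the egg coat genes, whose median log2 ratio of sperm over egg was 6.05 (4.63 to 8.35 over 10 genes). That 27 of the 32 oocyte list members (84.4%) lay above the 90th percentile of the sperm library, 3124.7, restates the pattern and decides nothing about RNA of oocytes in the sperm material. Ovarian follicle genes had a median of 81.5 but ran from 10.9 (foxl2) to 3837 (cyp11a1), and some of them are also testis genes, so they decide nothing here. A swap of the sperm and egg labels is argued against, since all 51 flagellum and testis genes were higher in the library labelled sperm, with a median log2 ratio of sperm over egg of 9.34 and median values of 3863 and 3.97. For the oocyte transcripts, RNA of oocytes, expression of these genes by the testis itself and a mixed sample stay open. The library also held marker transcripts of other tissues. All 13 members of the added exocrine pancreas list reached 10 in sperm, and 0 did in egg, 1k-cell or germ ring. Of 16 red blood cell genes 13 reached 10 in sperm, 1 in egg, 2 at the 1k-cell stage and 5 at the germ ring stage. The folds of egg against sperm therefore compare the 2 libraries and cannot be assigned to sperm cells alone.

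The library labelled egg holds 45 gene names at 500 or more, 12 of them clone-type names, that were at least 64-fold lower at the 1k-cell stage. Among them are keratin, claudin and collagen genes (krt5, krt15, cldni, col1a2). Others are the checkpoint gene bub3 (22159 in egg and 136 at the 1k-cell stage), trdmt1, msmo1, b2m, cd74a, rbp4 and apoeb. Of the 45 names 5 are in the added epidermis list. Reads leaked from the germ ring or sperm library are argued against for the genes that stood higher in egg than in that library. These were 40 of 45 for germ ring and 41 of 45 for sperm. The median log2 ratio over all 45 was 7.11 for egg over germ ring and 2.31 for egg over sperm, but a choice by high egg value raises both. For the rest leakage stays open, as for krt4 with 60446 at the germ ring stage and 5146 in egg. RNA of epidermis-type cells in the egg material is a candidate explanation: the added epidermis list had a median log2 ratio of egg over 1k-cell of 4.85, at percentile 100.00 of random lists, and 3.79 over the 25 members left without the 5 that belong to the pattern. Its most abundant member, zgc:92533 (now krt91), stood at 68072 in egg and 33.3 at the 1k-cell stage, but it is 1 of those 5 and so restates the pattern. No sort or gate that would remove epidermis-type cells is given in the labels. Clearance of stored egg mRNA stays equally open: 0 of 31 oocyte list members were at least 64-fold lower at the 1k-cell stage, but stored mRNAs can decay at different rates, so this neither excludes it nor tells it apart from other cells in the egg material.

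The median gene was 1.24 (log2) higher at the 1k-cell stage than in egg. The 100 most abundant genes taking the egg library's reads are argued against as the whole cause. The median stayed at 0.71 after the 142 genes among the 100 most abundant of either library were removed and totals were made equal. A wider set of abundant genes was not tested and stays open, since the 1000 most abundant took 70.4% of the egg total and 52.8% of the 1k-cell total. The lower depth of the egg library is argued against as well for abundant genes, with a median of 0.82 over 4015 of them after both libraries were thinned to 9241829 reads. Equal totals alone gave 0.89 over all genes compared, so part of the fall from 1.24 in both tests comes from the totals. The outcome of both was partly foreseeable from the scaling factors. Which scaling is right cannot be settled without spike-in RNA or replicates, since the amount of RNA per embryo and its poly(A) content may differ between stages.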
